A study of Mus musculus with 11 samples.

How the data were processed

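Chromatin immunoprecipitation with sequencing (ChIP-seq) recovers the DNA bound by a protein with an antibody, and places where the recovered DNA piles up are called peaks. The samples were purified splenic B cells of B1-8i mice, which carry a gene-targeted antibody specific for the hapten NP, on the 129 strain background. Per the labels' protocols, the cells were stimulated at 0.5 M cells per mL with NP-Ficoll (0.01 ng/mL), CD40L and the cytokines IL-2, IL-4 and IL-5. They were taken after 1 day, when activated, or after 3 days, following differentiation into plasma cells. Antibodies against IRF4 gave 3 libraries per day and antibodies against PU.1 gave 2 libraries per day. Library fragments of about 250 bp were sequenced on an Illumina Genome Analyzer 2. An input library, pooled from 2 preparations of peripheral or immature B cells, served the authors as background; it enters no comparison here.

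Per the series' design text, the authors mapped reads to mm9 and computed enrichment over input with the QuEST algorithms. The submitters' processing notes name the build mm9. The version of QuEST, its thresholds and the aligner are not given in the sources used here. Each deposited list holds 1 line per peak with its interval, a peak position and a maximum enrichment. That value is the authors' fold enrichment, a linear ratio to input, and it was used only to describe, rank or filter peaks within a list. The lowest fold enrichment in the authors' lists lay between 20.9 and 21.9 in the IRF4 day 1 libraries, between 15.0 and 16.9 in the IRF4 day 3 libraries and between 14.9 and 15.1 for PU.1, so the lists of the 2 IRF4 days do not end at the same level. The lists hold no read counts, so the sequencing depth behind each peak is unknown and no interval for single peaks is given.

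Peaks were called per library. There is also 1 list per factor and day, called the group list here. Each of its lines was found to be a copy of a line of a library list of that group with a partner peak in another library no more than 200 bp away. The IRF4 day 1 group list took 767 lines from replicate 1 and 1729 from replicate 2, the IRF4 day 3 list took 1772 from replicate 1 and 192 from replicate 2, and both PU.1 lists came from replicate 1 alone. Repeated lines, 7 in the PU.1 day 1 list and 5 in the PU.1 day 3 list, were counted once. Enrichments within an IRF4 group list therefore stem from 2 libraries and are not on a common scale. Replicates carry the number in the sample descriptions. The numbers in the sample titles differ for some libraries, and 2 libraries carry a pair of title numbers. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

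Peaks counted as shared when their positions were less than 200 bp apart. Union regions were built by merging positions of all libraries of a factor at the same distance. Chance overlap was measured by moving a list along each chromosome 1000 times. Motifs were searched on both strands of the 200 bp around the peak position in the mm9 reference sequence. They were the Ets-IRF composite element (EICE, GGAANNGAAA), the interferon-stimulated response element with a pair of IRF sites (ISRE, GAAANNGAAA), the AP-1-IRF composite element (AICE, GAAATGASTMA or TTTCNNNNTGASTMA), the AP-1 site (TGASTCA), a PU.1 site (GAGGAAGT) and a control sequence (AAAGNNAAGG). Background windows lay 2 kb to either side. The control sequence is the EICE pattern read backwards without complementing, so it holds the bases of the EICE. The ISRE holds more A and less G, and the control does not match its base composition. Positions are printed as deposited; whether they count from 0 or from 1 is not given in the sources used here. Motif coordinates were read from the reference and count from 1. No peak ended beyond its chromosome in that reference.

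Genes were the 22208 protein-coding genes of the GENCODE M1 annotation, which is on mm9. A gene was called bound when a group-list peak lay in it or within 20 kb of it. Distances of genes in the lists are to the start of the gene, and those of places chosen by rank to the nearest annotated transcript start. Being bound is a rule of distance and does not show that the peak acts on that gene. The 10 gene lists were fixed before the data were examined, and all 195 genes were matched, 1 of them through an older symbol. Bound genes of a list were compared with 10000 random lists of the same size, matched on gene length in 10 groups. A day-specific region is a group-list peak with no partner in the other day's group list. How many of these were called in a library of the other day, and how many PU.1 libraries had a peak at the named places, was counted after the results were seen.

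Values of libraries were compared between days with exact permutation tests, two-sided, which cannot go below 0.1 for 3 against 3 and 0.333 for 2 against 2 libraries. Their adjusted p-values cover 18 comparisons. Shares of regions were compared with two-sided Fisher's exact tests. Regions are not replicates, so these tests describe these lists. Benjamini-Hochberg adjustment covered 12 tests of motifs in day-specific regions, 14 tests of features by PU.1, 40 tests of gene lists, 20 tests of gene lists between days, 8 tests of PU.1 and start sites in day-specific and shared regions and 8 tests of motifs in PU.1 peaks by IRF4. Intervals of shares are Wilson 95% intervals and cover counting error only.

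Regions and genes named in the text follow a rule fixed before the data were examined. It takes the 5 peaks with the highest enrichment of each group list, the 5 highest found in every library of a day and in none of the other, and the 5 leading places shared by all 4 group lists, ranked by the sum of their ranks. From each gene list it takes up to 8 genes with a peak found in every library of an IRF4 day, and at most 4 genes with no peak. Other names are marked as chosen after their values were seen.

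Alternatives were other overlap distances (100 or 500 bp, or the deposited intervals), the stronger 50% of each list, equal numbers of top peaks per library (825 for IRF4 and 27321 for PU.1), regions found in at least 2 libraries, other motif windows, gene distances and start-site distances, each library left out in turn, and replicate blocks. With an IRF4 library left out, that day's group list became the regions called in both remaining libraries. With a PU.1 library left out, it became all peaks of the remaining library. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. For the tests chosen after the results were seen, the requirement that the libraries of the days must not overlap was itself added after their values were known. Before that, the ISRE gap with equal numbers had passed by a thin margin. The procedures were tested on simulated data. A planted overlap of 40% was returned as 40%, and 100% of 583 planted ISRE were found. In Fisher's exact tests equal motif shares passed p = 0.05 in 3.9% of 1000 draws. Random gene lists of 20 passed in 0.25% of 400 draws, while all 200 simulated lists with 9 bound genes passed. The gene-list test was conservative there, but simulated genes were bound independently of each other. The simulation therefore does not show how the test behaves where neighbouring genes share a peak.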

Results

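IRF4 is a transcription factor that B cells raise on activation and plasma cells keep at high levels; alone it binds DNA weakly, and it often binds beside a partner. PU.1 is an Ets-family factor of B and myeloid cells and 1 of these partners. The study asked where both factors sit in the genome of activated B cells before (day 1) and after (day 3) differentiation into plasma cells. There were 3 IRF4 libraries and 2 PU.1 libraries per day. The IRF4 libraries of day 1 held 825, 9326 and 8929 peaks and those of day 3 held 2784, 1408 and 5595 peaks. The PU.1 libraries held 27321 and 38052 peaks on day 1 and 34410 and 34061 on day 3. Coordinates are on mm9.

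IRF4 was found at introns of the B cell regulators Bach2, Pax5 and Ebf1 and near genes of antigen receptor signalling and antigen presentation on both days. A common core was bound in all 6 IRF4 libraries, but most places were not shared so widely. Of 20058 union regions of IRF4, 293 were called in every library and 79.1% in a single library. PU.1 was more uniform, with 14200 of 57563 union regions in all 4 libraries and 36.8% in a single library.

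The number of IRF4 peaks was 6360 ± 4798 (SD, n = 3) on day 1 and 3262 ± 2134 (SD, n = 3) on day 3. The difference of -3098 peaks was within the spread between libraries (exact permutation p = 0.4); it was -5865, -1615 and -1813 without day 1 replicates 1, 2 and 3. For PU.1 the difference was 1549 peaks (exact permutation p = 1, n = 2 per day), which turned to -3817 without day 1 replicate 1 and rose to 6915 without day 1 replicate 2. Libraries of the same day did not share measurably more than libraries of different days. The share of the shorter list with a partner was 64.9% ± 21.7 (SD, 6 pairs) within and 57.1% ± 18.5 (SD, 9 pairs) between days for IRF4 (exact permutation p = 0.2 over 10 splits). Without IRF4 day 3 replicate 3 the difference of 7.76 percentage points became 0.349, and without day 3 replicate 1 it was 12.4. For PU.1 the means were 71.6% within and 70.8% between days (exact permutation p = 0.667 over 3 splits), and the difference turned to -5.61 without day 1 replicate 1 and to -10.5 without day 1 replicate 2, and rose to 16.4 without day 3 replicate 2.

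**Figure D1:**
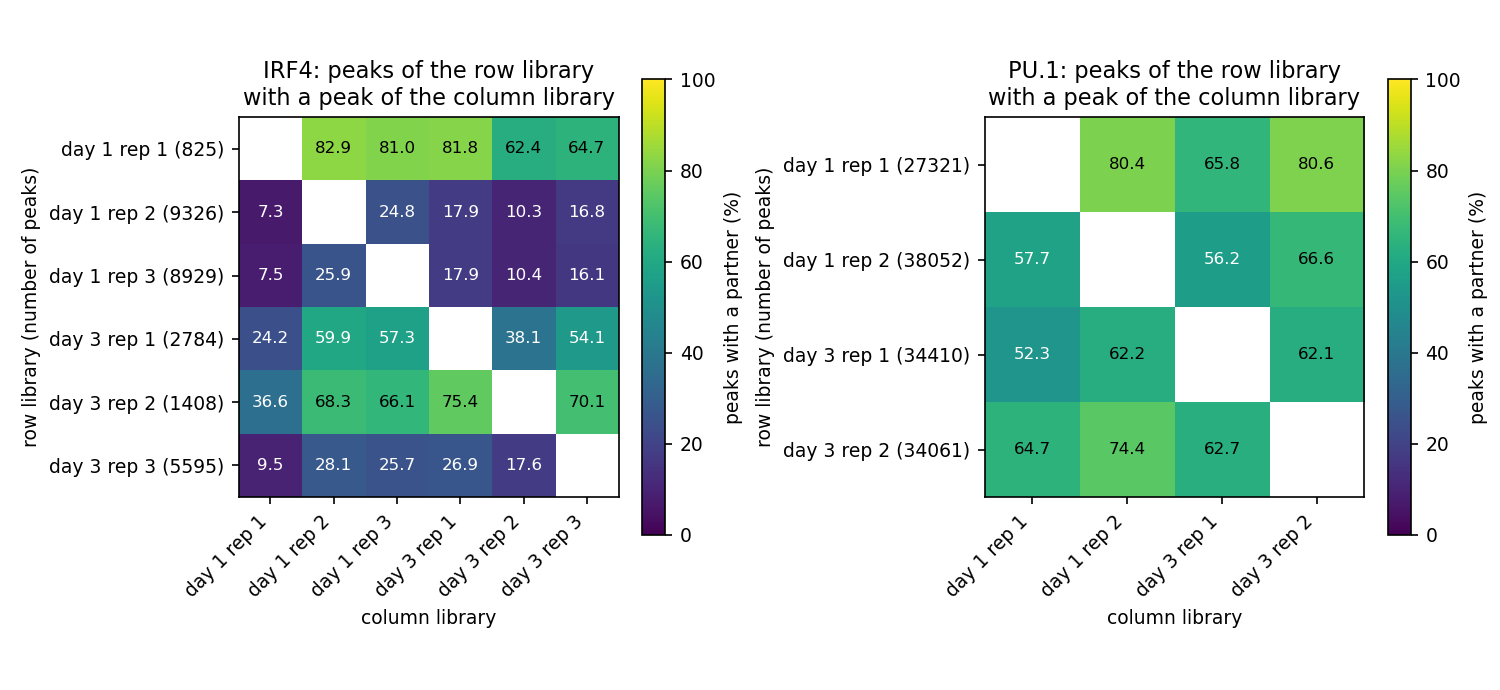
Percentage of the peaks of each row library that had a peak of the column library less than 200 bp away, for IRF4 (left) and PU.1 (right), with the number of peaks per library in brackets. The IRF4 day 1 library with 825 peaks had partners for 82.9% and 81.0% of its peaks in the other day 1 libraries, of whose 9326 and 8929 peaks 7.33% and 7.48% had a partner in it.

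Genes of the B lineage lay near IRF4 peaks more often than random genes of the same length. In the B cell receptor and identity list, 13 of 20 genes were bound on day 1 and 10 on day 3, against 2.45 and 2.12 in random lists. Of 17 antigen presentation and costimulation genes, 11 and 8 were bound, against 1.56 and 1.31. Neighbouring genes of this list share peaks (H2-DMa, H2-DMb1 and H2-DMb2 on both days, H2-Aa and H2-Eb1 on day 1), which the random lists do not mimic, so its p-value can be too small; the same holds for Tap1, Psmb8 and Psmb9 in the interferon list below. Of 20 plasma cell genes, 10 and 11 were bound, against 2.32 and 2.00. For these lists the permutation p was 0.0002, the smallest the test can give (adjusted p = 0.0008). Of 20 germinal centre genes, 9 were bound on day 1 (permutation test, adjusted p = 0.0008) and 6 on day 3 (adjusted p = 0.0459). Across all genes, 10.0% were bound on day 1 and 8.47% on day 3.

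Genes of activation and of the interferon response were bound in both lists as well. Of 20 NF-kB and activation genes, 8 were bound on each day (adjusted permutation p = 0.00123 and 0.00141), and of 23 interferon-stimulated genes 8 on each day (adjusted p = 0.00123 and 0.00141). With only the stronger 50% of each list, the activation genes on day 3 (permutation test, adjusted p = 0.152) and the interferon-stimulated genes on day 1 (adjusted p = 0.269) no longer passed. Among markers of other cells, myeloid markers counted 6 of 20 on day 1 (permutation test, adjusted p = 0.0251, and 0.234 with 5 kb and 0.101 with 50 kb around genes) and 3 on day 3 (adjusted p = 0.511). T and NK cell markers counted 1 and 2 of 20, and erythroid and megakaryocyte markers 0 of 15 on both days. Neuron and liver genes counted 1 of 20 on both days. Apart from the myeloid markers on day 1, none of these lists differed from random lists, but the test could hardly show too few bound genes. Random lists held 0.940 to 2.09 on average, and 0 of 15 still gave permutation p = 0.633 and 0.754. Genes bound by IRF4 on 1 day only numbered at most 8 in any list, too few for a test between days to pass after adjustment (exact binomial test, adjusted p = 1 for all 10 lists), so a difference between days is left open.

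PU.1 lay near many more genes, 52.3% of all on day 1 and 54.4% on day 3. All 20 B cell receptor and identity genes, all 17 antigen presentation genes and all 20 activation genes were bound on both days (adjusted permutation p of 0.00141 or less). Germinal centre genes counted 19 and 18 of 20 (permutation test, adjusted p = 0.00222 and 0.0192; on day 3 it was 0.157 with the stronger 50% of the list and 0.0541 with 50 kb around genes), and interferon-stimulated genes 19 of 23 on each day (adjusted p = 0.0156 and 0.0284). Plasma cell genes counted 16 and 17 of 20 (permutation test, adjusted p = 0.101 and 0.047). Their day 3 value was 0.516 with the stronger 50% of the list and 0.0873 with 5 kb around genes, and their day 1 value 0.0373 with 50 kb around genes. Myeloid markers counted 13 of 20 on each day, T and NK cell markers 13 of 20, erythroid and megakaryocyte markers 5 and 8 of 15, and neuron and liver genes 9 and 11 of 20, none apart from random lists; only the myeloid markers of day 1 passed with 50 kb around genes (permutation test, adjusted p = 0.0411).

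Among germinal centre genes, Bach2, a repressor of plasma cell differentiation, held 2 intronic places bound in all 6 IRF4 libraries. At chromosome 4, 32445615 to 32446062, the peak held the EICE GGAAGTGAAA (32445755 to 32445764, minus strand) and coincided with PU.1 peaks of both days; its enrichment was 97.4 in the day 3 list. At 32492172 to 32492507 it held the ISRE GAAACTGAAA and an AP-1 site; PU.1 was called there in 1 library of each day. A Bach2 intron peak at 32511514 to 32511797 was called in 3 day 1 libraries and 0 day 3 libraries. Pax5, which maintains B cell identity, was bound in an intron at chromosome 4, 44683859 to 44684229, with the EICE GGAACTGAAA and PU.1, in all 6 libraries. Ebf1, another B lineage regulator, was bound in an intron at chromosome 11, 44578575 to 44578894, in 3 day 1 and 2 day 3 libraries. Foxo1 held an AICE in an intron at chromosome 3, 52075357 to 52075693, in 3 day 1 and 2 day 3 libraries, and Mef2c an intronic peak at chromosome 13, 83711131 to 83711565, in 3 day 3 libraries and 1 day 1 library. Bcl6, Irf8 and Spib had no group-list IRF4 peak within 20 kb.

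Among plasma cell genes, Prdm1, which encodes the plasma cell regulator Blimp-1, was bound in an intron at chromosome 10, 44164272 to 44164596. That peak was called in 3 day 3 and 2 day 1 libraries, held the ISRE GAAAAAGAAA (44164341 to 44164350, plus strand) and had no peak in any PU.1 library. Another Prdm1 peak of the day 3 list, intergenic at 44154393 to 44154799, was called in 2 day 3 and 0 day 1 libraries. It coincided with PU.1 peaks in 2 libraries of each day. Irf4 itself had a peak 16.3 kb upstream, intergenic at chromosome 13, 30824584 to 30824875, in 3 day 3 libraries and 1 day 1 library. It held the same sequence GAAAAAGAAA as the Prdm1 intron peak (30824765 to 30824774, plus strand), and no PU.1 library had a peak there. Ern1, a sensor of the unfolded protein response, was bound in an intron at an EICE with PU.1 (chromosome 11, 106289521 to 106289950, 3 day 3 and 2 day 1 libraries). Tnfrsf13b and Ell2 had peaks in all 6 libraries, 17.7 kb upstream and in an intron. Zbtb20 had an intronic peak in 3 day 1 libraries and 1 day 3 library. Xbp1, Sdc1, Igj and Creb3l2 had none.

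**Figure D2:**
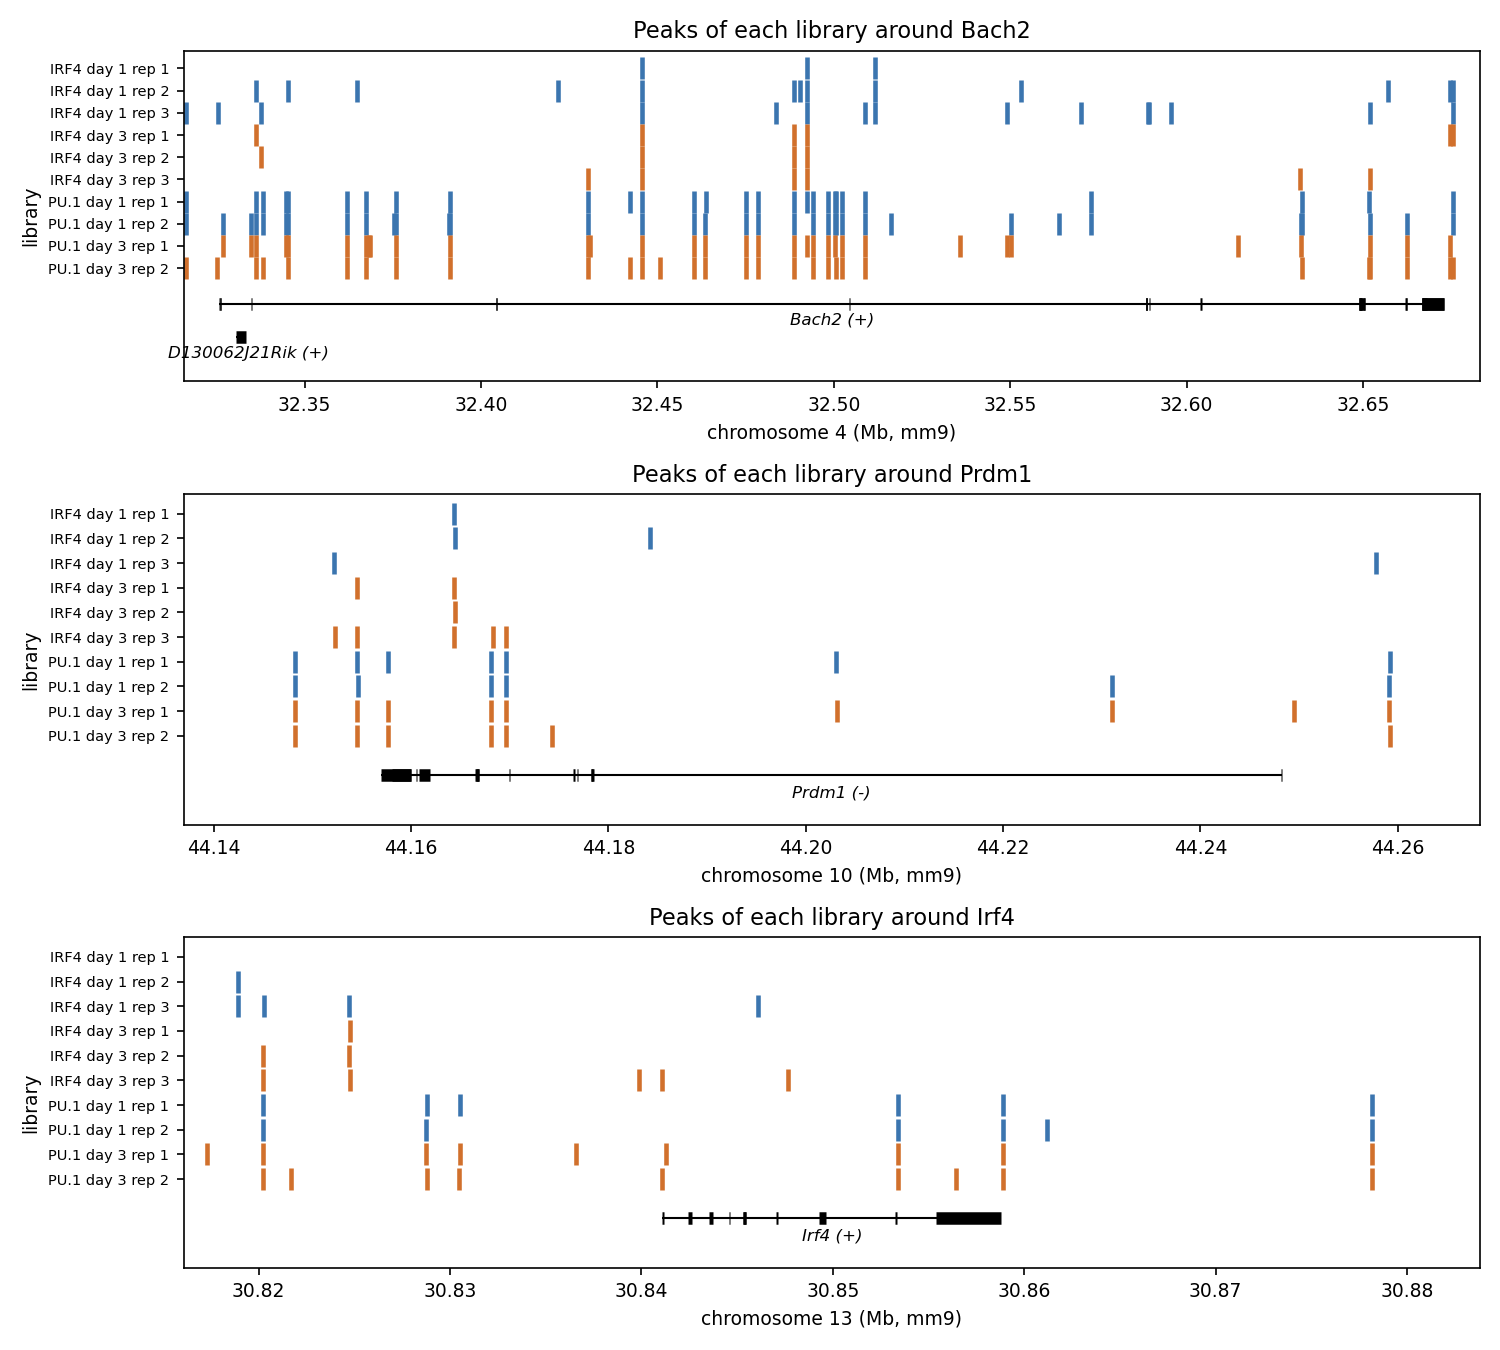
Peak positions (vertical ticks) of the 6 IRF4 and 4 PU.1 libraries on mm9 chromosome coordinates in Mb around Bach2, Prdm1 and Irf4, day 1 in blue and day 3 in orange, with protein-coding genes below (line) and their exons (boxes). The Bach2 intron places at 32445745 and 32492315 were called in all 6 IRF4 libraries, and the peak 16.3 kb upstream of Irf4 in 3 day 3 libraries and 1 day 1 library.

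In the receptor and identity list, the gene of the kinase Syk (Sykb in the annotation) had an intergenic peak 10.5 kb upstream in all 6 libraries, with PU.1 (chromosome 13, 52667922 to 52668205, enrichment 81.7 on day 3). Pik3ap1 was bound in an intron with PU.1 in all 6 libraries. Cd79b, a signalling chain of the B cell receptor, had an EICE peak 8.8 kb beyond its start site (chromosome 11, 106167158 to 106167520), and Blnk, an adaptor below the receptor, a peak 1.2 kb upstream of its start site, both in 3 day 3 and 2 day 1 libraries. Bank1 and Dapp1 each had an EICE peak with PU.1 in 3 day 3 libraries and 1 day 1 library. Btk, Cd22, Cd72 and Ptpn6 had no peak.

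In the antigen presentation list, Cd74, the invariant chain of MHC class II, had EICE peaks with PU.1 11.7 kb upstream (chromosome 18, 60951672 to 60951899, intergenic) and 27.3 kb beyond its start site in an intron of Tcof1 (60990692 to 60990985), both in all 6 libraries. Another EICE peak lay 0.1 kb upstream of its start site (60963274 to 60963502) in 3 day 1 libraries and 1 day 3 library. A peak 0.1 kb upstream of H2-DMb2, with an EICE and a PU.1 peak in 1 library of each day, was called in all 6 IRF4 libraries (chromosome 17, 34279942 to 34280380) and also lay within 20 kb of H2-DMa and H2-DMb1, so it counts for 3 genes of the list. Icosl had peaks in all 6 libraries. H2-Oa and Fcer2a each had a peak in 3 day 3 and 2 day 1 libraries. Rfx5 had an intergenic peak in 3 day 1 libraries and 0 day 3 libraries. Ciita, H2-Ab1, H2-Ob and Cd80 had none.

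In the activation list, an intron of Nfkb1 was bound in all 6 libraries (chromosome 3, 135328641 to 135329030). Myc had an EICE peak with PU.1 14.4 kb beyond its start site (chromosome 15, 61831139 to 61831464) in 3 day 1 and 2 day 3 libraries, and Traf1 and Batf had peaks in 3 day 3 and 2 day 1 libraries. Nfkb2, Relb, Nfkbie and Jun had none. In the interferon list, the promoter of Zbp1, a nucleic acid sensor, was bound 0.1 kb upstream of its start site in 3 day 3 libraries and 0 day 1 libraries (chromosome 2, 173044292 to 173044822), at 4 overlapping or neighbouring ISRE with a PU.1 peak in 1 day 3 library. Tap1, Psmb8 and Psmb9 shared 1 EICE peak in all 6 libraries (chromosome 17, 34317482 to 34317794). Irf1, Isg20, Ifit2 and Ifit3 had none. In the lists of other cells, 1 gene each of the myeloid, T and NK cell, and neuron and liver lists had a peak in every library of a day. Tlr4 was bound in an intron in all 6 libraries, Ctla4 in an intron in 3 day 3 libraries and 0 day 1 libraries, and Gad1 62.1 kb from its start site in 3 day 3 and 2 day 1 libraries.

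The IRF4 group lists of the days overlapped in part. Of 1964 IRF4 peaks on day 3, 56.2% (95% interval 54.0 to 58.3) had a day 1 partner, leaving 861 without one. Of 2496 peaks on day 1, 44.2% had a day 3 partner, leaving 1393 without one. A peak without a partner in the other group list was often called in a single library of that other day, in 54.0% of the 861 and 39.4% of the 1393 cases, so the lack of a partner in the other list does not by itself show a gain or loss of IRF4. The day 3 group list also reaches down to an enrichment of 16.4 and the day 1 list to 20.9. Weak day 3 peaks may lack a day 1 partner for that reason. Moved lists gave 0.0393% and 0.0327%. With only the stronger 50% of each list the share of day 3 peaks with a day 1 partner was 41.5%, and with equal numbers of top peaks it was 45.3%. For PU.1, 66.1% of 21382 day 3 peaks had a day 1 partner (7238 had none) and 64.3% of 21966 day 1 peaks a day 3 partner (7834 had none). Of the PU.1 peaks without a partner, 69.6% of the 7238 and 82.4% of the 7834 were called in a library of the other day, and the same limit applies.

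The strictest count takes regions called in every library of a day and in none of the other. For IRF4 there were 38 such regions on day 1 and 72 on day 3, 110 together, and splits of the 6 libraries that mix the days gave up to 252. The leading day 3 regions lay in an intron of Ctla4 (chromosome 1, 60970127 to 60970559, with 2 AICE), 26.5 kb upstream of Tox2, in an intron of Oxr1 (chromosome 15, 41663721 to 41664266, with an ISRE), 0.1 kb upstream of the interferon-inducible gene Ifi204 (chromosome 1, 175697071 to 175697279, with an ISRE) and in an intron of Itga5. Of these 5, the Itga5 region held a PU.1 peak in all 4 libraries and the Tox2 region in 1 day 3 library. The leading day 1 regions lay 10.6 kb upstream of Pcif1 and past the end of Ebf1, 204.8 kb from its nearest annotated start site, both with an EICE, 26.3 kb upstream of Ppp4r2 and in introns of Asph and Map4k4. These counts depend on single libraries. Without IRF4 day 1 replicate 1, which held 825 peaks, the day 1 count was 815; without day 3 replicate 1 it was 93. The day 3 count was 140 and 138 without day 1 replicates 2 and 3, and 144 and 288 without day 3 replicates 1 and 2.

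In the group lists, PU.1 was found at 56.8% of 2496 IRF4 peaks on day 1 (95% interval 54.8 to 58.7) and at 64.1% of 1964 on day 3 (95% interval 61.9 to 66.1), against 0.357% and 0.346% with moved lists. Regions in the IRF4 lists of both days had PU.1 most often, 75.2% in the day 1 list, against 42.2% of the day 1-specific regions (Fisher's exact test, adjusted p = 2.19e-62). Of the 861 day 3-specific regions, 60.05% had PU.1 on day 3 and 63.3% had PU.1 in the day 1 list. The 5 leading places of all 4 lists lay in introns of Snx29, Setbp1, Acoxl and Ndst1 and 28.1 kb from the nearest start site, that of Med21, and 4 of them held an EICE. In all, 697 IRF4 day 1 peaks lay in all 4 lists.

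The excess of PU.1 at day 3-specific over day 1-specific regions was 17.8 percentage points (Fisher's exact test, p = 2.04e-16). It rested on the long day 1 lists. Without IRF4 day 1 replicate 2 it was -1.01 and without replicate 3 it was -0.905 percentage points, with 143 and 149 day 1-specific regions left. Across libraries the share of IRF4 peaks with same-day PU.1 was 77.7%, 26.4% and 24.8% on day 1 and 56.2%, 66.0% and 41.3% on day 3. The means of 43.0% ± 30.1 and 54.5% ± 12.5 (SD, n = 3 each) did not differ beyond the spread (exact permutation p = 0.6). The difference of 11.5 percentage points was 28.9, 3.25 and 2.46 without IRF4 day 1 replicates 1, 2 and 3, and 5.80 and 18.2 without IRF4 day 3 replicates 2 and 3. It was 24.4 without PU.1 day 3 replicate 1, where the PU.1 day 3 list held all 34061 peaks of the remaining library. With the 825 top peaks of each library the difference was -0.0808 percentage points.

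IRF4 peaks with and without PU.1 held different sequence elements. Without PU.1 means no partner in the same-day PU.1 group list, which holds peaks found in both PU.1 libraries. Places called in only 1 PU.1 library, such as the EICE peak at H2-DMb2, therefore count as without PU.1 and may not be free of it. On day 1 the EICE was present in 36.0% of 1417 IRF4 peaks with PU.1 and in 3.71% of 1079 without (Fisher's exact test, adjusted p = 9.4e-96), and the AP-1 site in 14.8% and 38.1% (adjusted p = 2.07e-39). On day 3 the EICE was present in 38.5% of 1258 peaks with and 14.9% of 706 without PU.1 (Fisher's exact test, adjusted p = 3.79e-29), and the AP-1 site in 12.0% and 29.6% (adjusted p = 9.33e-21). The AICE was also rarer with PU.1, 2.61% against 8.90% on day 1 and 1.67% against 8.36% on day 3 (exact tests, adjusted p = 8.05e-12 and 4.94e-12). An AICE that ends in TGASTCA holds the AP-1 site as well, so the AICE contrast is in part the AP-1 contrast. The ISRE was in 10.2% with and 17.4% without PU.1 on day 3 (exact test, adjusted p = 9.3e-06), and in 6.70% and 8.62% on day 1 (adjusted p = 0.0997), where all 3 libraries had the opposite sign (-0.343, -2.22 and -3.24 percentage points, without minus with PU.1). Flanking windows held an EICE in about 2% of cases. All of these are Fisher's exact tests over peaks of the group lists. In each of the 6 libraries the EICE was more frequent with PU.1 and the AP-1 site more frequent without it. For the AP-1 site that excess was 29.2, 3.25 and 2.44 percentage points in day 1 replicates 1, 2 and 3. On day 3 it was 19.5, 16.0 and 3.43. The longest lists thus showed little of the group-list contrast. The AICE excess was likewise 12.2, 0.893 and 0.723 on day 1 and 6.38, 6.63 and 1.41 on day 3.

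In the day 3 libraries IRF4 peaks held the ISRE more often. The share was 6.79%, 5.52% and 5.20% in the day 1 libraries and 11.6%, 12.6% and 12.8% in the day 3 libraries. The means were 5.84% ± 0.84 and 12.4% ± 0.63 (SD, n = 3 each), a difference of 6.52 percentage points with no overlap between days (exact permutation p = 0.1, the smallest possible for 3 against 3; adjusted p = 0.75 over 18 comparisons). Among group-list regions the ISRE was in 6.96% of day 1-specific, 8.25% of shared and 18.0% of day 3-specific regions (difference 11.04 percentage points, Fisher's exact test, adjusted p = 1.51e-14). With the stronger 50% of each list that difference was 5.89 percentage points (exact test, adjusted p = 0.000386). The control sequence was in 1.64% ± 0.50 and 2.11% ± 0.09 of library peaks (SD, n = 3 each; exact permutation p = 0.2).

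**Figure D3:**
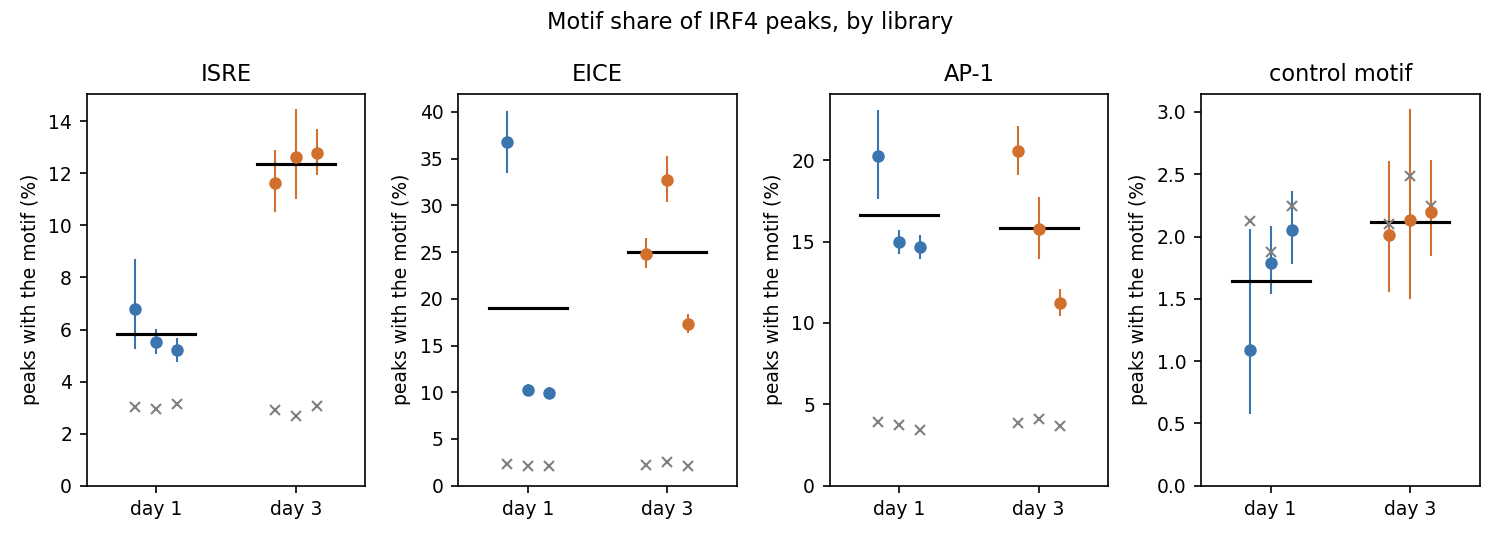
Percentage of the IRF4 peaks of each library (points, with Wilson 95% intervals; black lines are means, grey crosses the same windows 2 kb away) that held the ISRE, EICE, AP-1 site or control sequence within 200 bp around the peak position. The ISRE points of day 3 lie between 11.6% and 12.8%, above those of day 1 at 5.20% to 6.79%, while the points of the days overlap for the EICE and the AP-1 site.

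The AP-1 site was less frequent in day 3-specific regions. It was in 27.9% of day 1-specific, 21.1% of shared and 13.9% of day 3-specific regions (difference -13.9 percentage points, Fisher's exact test, adjusted p = 1.88e-14), and the difference was -8.29 without IRF4 day 1 replicate 2, -8.15 without replicate 3 and -9.02 in windows of 100 bp. Library means were 16.6% ± 3.1 and 15.9% ± 4.7 (SD, n = 3 each; exact permutation p = 1). That difference of -0.769 percentage points was -7.47 with equal numbers of top peaks (24.5% and 17.1%, exact permutation p = 0.2) and -3.45 with the stronger 50% of each list, but turned to 0.291 in windows of 100 bp, to 1.04 without IRF4 day 1 replicate 1 and to 1.54 without day 3 replicate 3. The EICE was in 13.7% of day 1-specific, 32.5% of shared and 26.8% of day 3-specific regions (exact test, adjusted p = 7.56e-14). That difference of 13.1 percentage points fell to 1.65 without IRF4 day 1 replicate 2 and to -0.282 without replicate 3, and library means of 19.0% ± 15.4 and 24.97% ± 7.7 (SD, n = 3 each) overlapped (exact permutation p = 0.6). The library difference of 6.003 was 14.9, 1.65 and 1.48 without IRF4 day 1 replicates 1, 2 and 3, 2.12 and 9.82 without day 3 replicates 2 and 3, and 3.96 with equal numbers. The AICE differed by -2.60 percentage points (exact test, adjusted p = 0.00402), which kept its sign but did not pass 0.05 without day 1 replicate 2 (-3.45), day 1 replicate 3 (-1.20), day 3 replicate 1 (-1.91) or day 3 replicate 3 (-2.18), where fewer regions were compared, with the stronger 50% of each list (-0.534) or in windows of 100 bp (-0.774). The PU.1 site differed by 7.24 percentage points (exact test, adjusted p = 3.43e-08), which kept its sign but did not pass 0.05 without day 1 replicate 2 (3.41) or replicate 3 (4.43). The control sequence itself differed by 1.96 percentage points (1.29% and 3.25%, exact test, adjusted p = 0.00289).

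**Figure D4:**
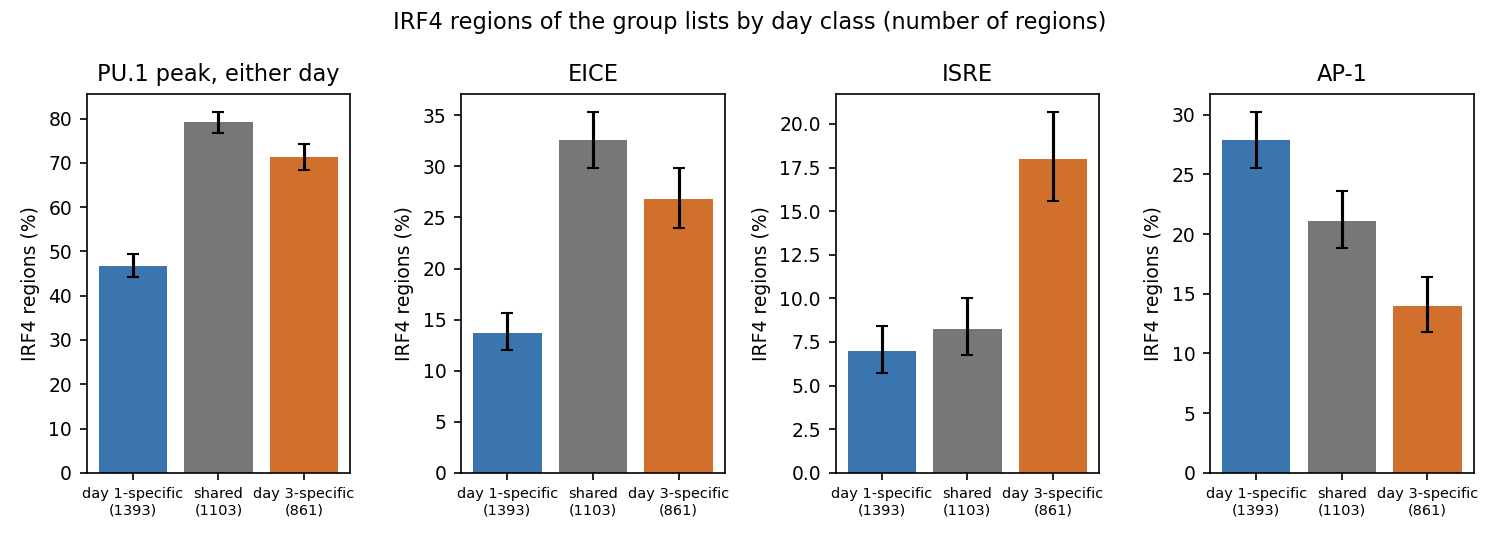
Percentage of IRF4 regions with a PU.1 peak of either day, an EICE, an ISRE or an AP-1 site (bars, with Wilson 95% intervals) in the 1393 day 1-specific, 1103 shared and 861 day 3-specific regions of the group lists. The ISRE rises to 18.0% and the AP-1 site falls to 13.9% in day 3-specific regions, while PU.1 and the EICE are most frequent in shared regions at 79.3% and 32.5%.

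PU.1 shared 3 of its 5 highest places between the days. The day 1 and day 3 lists were both headed by a place 7.6 kb upstream of Cd244 (chromosome 1, 173481372 to 173481926, intergenic), and both had an untranslated region of the leukocyte gene Cd53 and a place 38.5 kb from the nearest start site, that of Nnmt, among the 5 highest. A place 15.6 kb upstream of Siglecg, a B cell inhibitory receptor, held both an EICE and a PU.1 site. Regions called in both PU.1 libraries of a day and in none of the other numbered 1370 on day 1 and 2176 on day 3, 3546 together, and the other splits of the 4 libraries gave 3535 and 3654. Without single libraries the counts were 2746 to 8846 and 3810 to 10520. The highest day 1 region lay in an intron of Tcf4, a B lineage regulator (chromosome 18, 69821782 to 69823104), and the highest day 3 region in an intron of Hivep3 (chromosome 4, 119726774 to 119727443), close to another Hivep3 region called on day 1 only (119726194 to 119726577).

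Day 3-specific PU.1 regions lay within 1 kb of a start site in 25.8% of 7238 cases and day 1-specific ones in 10.3% of 7834, a difference of 15.6 percentage points (Fisher's exact test, p = 1.18e-140). That difference was 3.55 percentage points without PU.1 day 3 replicate 1, 9.12 without day 1 replicate 1 and 32.7 with the stronger 50% of each list. Leaving out a PU.1 library puts all peaks of the remaining library in that day's list, on day 3 34061 without replicate 1 against 21382 before. The values without a library therefore mix its loss with a longer list, and the part of either cannot be told. The library values were 15.8% and 17.2% on day 1 and 23.7% and 17.3% on day 3 (exact permutation p = 0.333, the smallest possible for 2 against 2). The PU.1 site was in 26.8% of day 1-specific and 19.2% of day 3-specific regions (difference -7.63 percentage points, exact test, adjusted p = 1.38e-27), and -3.11 without PU.1 day 3 replicate 1. The EICE fell by 2.76 percentage points (exact test, adjusted p = 2.36e-07), but the sign turned without day 1 replicate 1 (1.99) or day 3 replicate 1 (2.34). For both motifs the values without a library rest on the same longer lists. IRF4 peaks lay within 1 kb of a start site in 10.4% ± 1.6 of cases on day 1 and 12.2% ± 2.3 on day 3 (SD, n = 3 each; exact permutation p = 0.5; the difference of 1.79 percentage points was 0.869 without day 1 replicate 1 and 0.488 without day 3 replicate 3), and in 10.9% of day 1-specific and 12.3% of day 3-specific regions (Fisher's exact test, p = 0.308), where the difference of 1.40 percentage points became 4.26 (p = 0.0222) without IRF4 day 3 replicate 1.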

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

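The 2 tests of technical explanations in this part were chosen after the result was seen. A PU.1 peak is here a peak of the same-day PU.1 group list, so a place called in only 1 PU.1 library counts as without. In the 3 IRF4 libraries of day 1, peaks without a PU.1 peak held the ISRE less often than peaks with one, by -0.343, -2.22 and -3.24 percentage points; in the 3 libraries of day 3 they held it more often, by 4.12, 8.37 and 3.94 percentage points. Every library of a day thus lay on the opposite side of 0 from those of the other day. These opposite sides were the rule that picked the ISRE from the 6 motifs and the share near start sites, so they add no evidence. The gap was -1.93 ± 1.47 on day 1 and 5.48 ± 2.51 on day 3 (SD, n = 3 each). The difference was 7.41 percentage points (exact permutation p = 0.1, the smallest possible, adjusted p = 0.75 over 18 comparisons). The day 1 group list itself had the other sign, 6.70% with and 8.62% without PU.1. The gap also moved by 8.93 percentage points for the EICE and by 2.02 for the PU.1 site (exact permutation p = 0.1 each), without changing sides. For the AICE, AP-1 site, control and start sites the exact permutation p was 0.7 or more.

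Peaks near start sites as the source are argued against, since the difference was 7.09 percentage points among peaks over 1 kb from a start site, with no overlap between the days, although 1 of 3 day 1 libraries then lay above 0. List length stays open. With the same number of top peaks per library the difference was 6.68 percentage points, but the libraries of the days overlapped (exact permutation p = 0.2) and 1 of 3 day 1 libraries lay above 0, so the weak peaks of the long day 1 lists cannot be told apart from a change between the days. A use of the ISRE without PU.1 after differentiation is a biological hypothesis and was not tested apart from list length.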

How the results depend on the processing

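The restriction to peaks over 1 kb from a start site was chosen after the data were seen; the other alternatives were fixed before the data were examined. Of 328 values for the 29 results that answer a comparison, 276 kept direction and side of the threshold or stayed within their limits, and of 668 values for other results 561 did. Comparisons of libraries cannot reach 0.05 under any alternative, so for them only the direction counts here, however far the value moved. The causes were not tested unless given. Lists without read counts leave depth unknown, and 1 short IRF4 day 1 list (825 peaks) limits what its day can share.

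The share of the IRF4 day 3 list with a day 1 peak was 53.5% with intervals covering 50% of each other, 41.5% with the stronger 50% of each list and 45.3% with equal numbers; for PU.1 it was 62.5%, 69.7% and 65.1%, and 65.3% and 67.1% with distances of 100 and 500 bp. With the stronger 50%, regions exclusive to day 1 and day 3 numbered 19 and 33 for IRF4 and 451 and 934 for PU.1, fewer peaks being compared; with equal numbers the IRF4 day 3 count was 45. With libraries left out in turn the counts ranged from 44 to 815 and from 85 to 288 for IRF4 and from 2746 to 8846 and from 3810 to 10520 for PU.1, since fewer libraries had to share a region or lack it.

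Ranges with libraries left out, for day 3 minus day 1 in percentage points, were 1.48 to 14.9 (IRF4 EICE), 2.46 to 28.9 (IRF4 with PU.1), -0.358 to 1.09 (IRF4 AICE), -3.12 to 1.54 (IRF4 AP-1), and among day-specific IRF4 regions -1.01 to 31.4 (PU.1 peak), 1.22 to 4.26 (start sites), -0.282 to 14.0 (EICE) and -3.45 to -1.20 (AICE). Peak numbers ranged from -5865 to -1615 (IRF4) and from -3817 to 6915 (PU.1), and overlap differences from 0.349 to 12.4 (IRF4) and from -10.5 to 16.4 (PU.1). For PU.1 libraries the ranges were -2.00 to 0.579 (EICE), -0.219 to 0.830 (ISRE) and -0.0149 to 0.0772 (AICE), and for PU.1 day-specific regions -6.57 to 2.34 (EICE), -0.675 to 1.89 (ISRE), -0.0766 to 0.120 (AICE) and -0.0221 to 0.4001 (control). The ranges of PU.1 regions rest on lists that hold all peaks of a remaining library.

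With equal numbers the IRF4 AICE difference was -1.21, the share with PU.1 -0.0808 and the PU.1 region ISRE -0.00477. With the stronger 50% the IRF4 AICE was -0.229, its region difference -0.534, and for PU.1 the AICE was -0.0016, the region ISRE -0.097 and the region control -0.272. In windows of 100 bp the IRF4 AP-1 difference was 0.291, the region AICE -0.774, the PU.1 EICE 0.0746, the control -0.011 and the region control -0.0425 (-0.0041 in 400 bp). Bound minus random genes turned for T and NK markers to 0.0189 (IRF4 day 1), -1.33 and -1.30 (PU.1) and for erythroid markers to -2.02 with the stronger 50%; with 5 kb to -1.60 and -2.78; with 50 kb to 2.45 and -0.937 (IRF4, T and NK) and 0.292 (PU.1, neuron and liver).

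The replicate numbers showed no clear pairing of the libraries. Deviations of same-numbered libraries correlated at -0.268, 0.077 and -0.103 for IRF4 and -0.003 for PU.1. Not every library correlated best with its own number. IRF4 libraries with the same title number correlated at 0.063 and 0.083. With 2 PU.1 libraries per day every pair gives the same value up to its sign, so the PU.1 values cannot show or exclude a pairing. With the description number as a replicate block the ISRE difference of 6.52 had an exact p of 0.25, the smallest possible with 3 blocks, so no call could change. The title number as a block also drops day 1 replicate 1 and day 3 replicate 3, and its values reflect both changes: start sites -0.427, AP-1 3.35, EICE 18.7, share with PU.1 35.5 and peak number -7031.5.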

Other observations

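Chosen after the results were seen were the comparison of PU.1 peaks by IRF4, the distances between peak positions, and the tests of explanations for the ISRE in this part, with their limits; the equal numbers and the control sequence used in them had been planned, the restriction by start sites had not. The tests of the EICE, of shared artefacts, of promoters and of other splits were fixed before. PU.1 peaks that IRF4 joined differed from the rest in sequence. They were 6.45% of PU.1 peaks on day 1 and 5.88% on day 3. The EICE was in 36.8% of the joined and 12.8% of the other PU.1 peaks on day 1, and in 38.9% and 11.9% on day 3 (Fisher's exact tests, adjusted p = 1.59e-105 and 2.98e-120). The PU.1 site GAGGAAGT went the other way, 16.4% against 27.6% on day 1 and 18.0% against 24.6% on day 3 (exact tests, adjusted p = 2.28e-21 and 5.07e-08). The excess was not particular to the EICE. The AP-1 site was in 12.4% against 5.62% on day 1 and 10.7% against 5.31% on day 3 (exact tests, adjusted p = 3.48e-20 and 7.73e-13). The ISRE was in 6.99% against 5.64% and 9.46% against 5.46% (exact tests, adjusted p = 0.0384 and 5.07e-08).

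Where the EICE was present, IRF4 and PU.1 positions lay at a median distance of 24 bp on day 1 (510 peaks, quartiles 11 and 41) and 17 bp on day 3 (484 peaks, quartiles 8 and 32). At places with an AP-1 site or AICE and no EICE the median was 43 bp on day 1 (171 peaks) and 31 bp on day 3 (120 peaks), and at places with none of these elements 29 bp (736 peaks) and 22 bp (654 peaks), close to the values with the EICE. The difference between these groups was not tested. Ifit1, an interferon-stimulated gene chosen after its values were seen, had a promoter peak with 2 ISRE in 2 libraries of each day (chromosome 19, 34715087 to 34715617).

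The first pattern weighed is the share of IRF4 peaks with a motif on each day. For the ISRE across libraries, list length and peaks at start sites are argued against. With equal numbers of top peaks the difference was 5.09 of 6.52 percentage points with no overlap between days. Among peaks over 1 kb from a start site it was 6.16. Base composition stays open. The control sequence differed by 0.470 across libraries, but it has the bases of the EICE and not those of the ISRE. Among day-specific regions the control rose from 1.29% to 3.25% as the ISRE rose from 6.96% to 18.0%. More frequent IRF4 binding at the ISRE in differentiated cells is therefore a hypothesis, found and tested on the same libraries. For the EICE the difference of 6.003 percentage points became 3.96 ± 3.95 (SE) with equal numbers, so list length and day cannot be told apart in 3 libraries per day.

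The second pattern is the joint presence of IRF4 and PU.1. Shared artefact regions without binding sites are argued against as the source of all joint peaks. The EICE share of IRF4 peaks with PU.1 was 18.2 times that of their flanks on the day with the lower ratio. The lower limit of 17.0 counts error in the peak share only and takes the flank share as exact. Joint peaks without an EICE are not covered by this test, so artefacts among them stay open. Open promoters are argued against as well, since at most 11.4% of IRF4 peaks with PU.1 lay within 1 kb of a start site. Binding as a pair at the EICE may account for the 36.0% and 38.5% of such peaks that hold it, as a hypothesis; the remainder was not explained by any test.

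The regions called in every IRF4 library of a day and in none of the other numbered 110 over both directions. The 10 splits of the 6 libraries are too few for a share under 0.05; 4 gave as many, the real one included, and the highest other split gave 252. The split with 252 set day 1 replicates 2 and 3 and day 3 replicate 1 against the rest. For PU.1 the real split gave 3546 regions and the others 3535 and 3654.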
